A study of Danio rerio with 7 samples.

How the data were processed

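DNA of 7 whole adult zebrafish was hybridised, 1 fish per array, to Agilent tiling arrays carrying 966836 non-control spots and 2974 control spots. Per the labels' protocols, DNA and RNA were extracted together with Trizol, 1 µg of DNA was denatured at 95 °C for 5 min in place of enzyme digestion, the reference was labelled with Cy3 and each fish with Cy5. No dye swaps were made, so a dye effect of a probe is shared by all 7 arrays.

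Per the file headers, the authors' arrays were read with Agilent Feature Extraction 10.5.1.1, which subtracted background, removed spatial trends and scaled each dye by a linear factor to give processed signal intensity per spot. A multiplicative trend was also fitted; its fit value was above 0 on 5 arrays and 0 on those of males 8 and 9. The deposited value table held the extractor's log10 ratios of Cy5 over Cy3 with a largest difference of 0 on all 7 arrays, and its column medians lay between -0.00783 and 0. These log10 ratios differed from the ratio of the processed signals at 0.933% to 1.33% of spots, where the extractor puts a substitute signal. Raw median spot and background intensities were also deposited and served for an alternative correction. The arrays were scanned in 3 sessions: males 8 and 9 in session 1, females 7, 8 and 9 in session 2, and female 4 and male 5 in session 3. Each array was on its own slide.

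The files of female 4, male 5 and male 8 gave probe positions of the Zv8 assembly and those of the other 4 fish positions of Zv7, although the headers named Zv7 in all 7. Probes were matched by name, and all arrays were analysed with Zv8 positions. In Zv7, 13.4% of the probes lay on another chromosome and 5.30% on unplaced sequence, and 51.2% of the chromosome 4 probes were on chromosome 4, so positions on that chromosome depend on the assembly. The files named no genes and no genome of either build was used here, so regions are named by position; the planned test of 28 gene lists was not run.

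From the processed signals, log2 of Cy5 over Cy3 was taken, spots marked as outliers by the extractor were dropped (0.0713% to 0.612% per array), repeated spots of 999 probes were averaged, and each array was centred on its median. Single probes over 4 noise SDs from the median of their 11 neighbours were pulled in to that limit. Each chromosome was segmented by penalised least squares (PELT) with a penalty of 2 times the noise variance times the natural log of its number of probes. Segments of at least 5 probes with a mean of at least 0.3 or at most -0.3 were called gains or losses. Calls of the 7 fish that shared a probe were merged into regions. Segmentation was tested on simulated data with 600 segments implanted per fish in shuffled arrays; at a log2 shift of 0.58 it found 0.213%, 3.84% and 42.9% of segments of 5, 10 and 25 probes, so single-copy gains are under-counted.

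The spread between siblings was the SD over the 7 fish of a region's mean, set against 10000 random windows of equal size outside all regions. These windows hold no call in any fish, while a region needs a call in at least 1, so the comparison is conditioned on the calls and its p-values serve only to rank and count regions. Females and males were compared with limma (lmFit, eBayes with a trend) on windows of 25 probes and on regions, with the Benjamini-Hochberg procedure at 0.05. Single values were compared by exact permutation over the 35 splits of 7 fish into 4 and 3. The share of chromosome 4 was tested with 1000 circular shifts. The windows test was tested on simulated data with independent normal noise, in which 1 of 38304 unchanged windows was called. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Numba 0.67.0, R 4.3.3 and limma 3.58.1 were used.

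Tests, thresholds, groups and the rule for the regions to name were fixed before the data were examined. The rule named the 12 regions with the largest absolute mean among those called in all 7 fish, the 12 with the largest SD among those varying between siblings, and, for sex, up to 10 windows and regions that passed or else the 3 with the smallest p. The alternatives fixed then were normexp correction, the deposited value table, removal of probes dim in the reference, subtraction of a long running median over 2001 probes, other penalties, thresholds, sizes and merging rules, null windows of the same chromosome, replicate number or scan session as a block, and leaving out each fish. Normexp used median spot signals with an offset of 50, because the files gave no mean spot signals. Alternatives added after seeing the data were a local running median over 201 probes, regression on probe length, scaling by array slope, Zv7 positions, leaving out both arrays of session 3, and segmenting the deviations from the probe's median over fish. The array slope was that of a fish's region means on the median fish, over the regions called in all 7.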

Results

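Genomic DNA of 7 adult zebrafish was compared with DNA of 1 common reference by two-colour array comparative genomic hybridisation, in which the dye ratio at each probe follows the relative number of copies of its sequence. The fish were full siblings of a hybrid strain, bred from the AB laboratory strain and a parent whose strain the labels call unknown. There were 4 females, numbered 4, 7, 8 and 9, and 3 males, numbered 5, 8 and 9, and each number named a separate animal. The reference was a hybrid DNA whose make-up was not given in the sources used here. The study asked whether differences in copy number between siblings went with differences in gene expression; the expression data were not analysed here. Each fish had 1 array, read at 962840 probes with a median spacing of 1375 bp on the 25 chromosomes of the Zv8 assembly. Positive log2 ratios stand for more copies in the fish than in the reference. The fish's own signal was well above background at 84.7% of spots for male 9 and at up to 96.7% for female 4, and the reference signal at 85.4% for male 8 to 94.5% for female 8. The probe-to-probe noise of the log2 ratio had an SD of 0.385 for male 9 to 0.529 for female 7, and the number of arrays limits the precision of every comparison below.

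The first question was how much of each sibling's genome differed in copy number from the reference. Every fish carried both gains and losses, and losses outnumbered gains in 6 of the 7 fish. Female 4 had 530 gains and 837 losses, female 7 had 677 and 801, female 8 had 678 and 931, and female 9 had 656 and 946. Male 8 had 316 gains and 446 losses, and male 9 had 357 and 396. Male 5 stood apart with 2260 gains and 1541 losses, which covered 25.6% of its probes against 2.04% to 7.49% in its siblings. The median fish had 656 gains and 837 losses, and the median call was 16.1 kb long in female 8 and 36.5 kb long in male 5. Without male 5 the mean was 536 ± 164 gains and 726 ± 243 losses per fish (SD, n = 6). Females had 1514 ± 115 calls (SD, n = 4) and males 1772 ± 1757 (SD, n = 3), and the difference was within the spread between fish (two-sided exact permutation test over 35 splits, p = 0.857, with 0.0571 the smallest p possible). Without male 5 the direction turned: males 8 and 9, the 2 arrays of scan session 1, whose ratios were smaller, had 762 and 753 calls, against 1367 to 1609 in the females. Arrays with shuffled probe order gave a mean of 1.2 calls for male 5 to 14.8 for female 8. Shuffling also breaks up any wave along the chromosome, so these counts cover independent probe noise only. Short events were mostly missed: of segments implanted in the shuffled arrays with a log2 shift of -1.0, 6.82% were found at 5 probes, 54.8% at 10 probes and 98.3% at 25 probes. At 10 probes the share found was 5.97% in the lowest fish and 91.0% in the highest, so these implants were missed unequally between arrays. Each array received the same shift, although real ratios were smaller in males 8 and 9 (array slopes 0.60 and 0.57). The shares therefore do not give how many real events were missed on these 2 arrays. The count of gains fell to a median of 215 when probes dim in the reference were left out. With normexp background correction the order turned: the median fish had 841 gains and 725 losses, and losses outnumbered gains in 3 of the 7 fish.

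**Figure D1:**
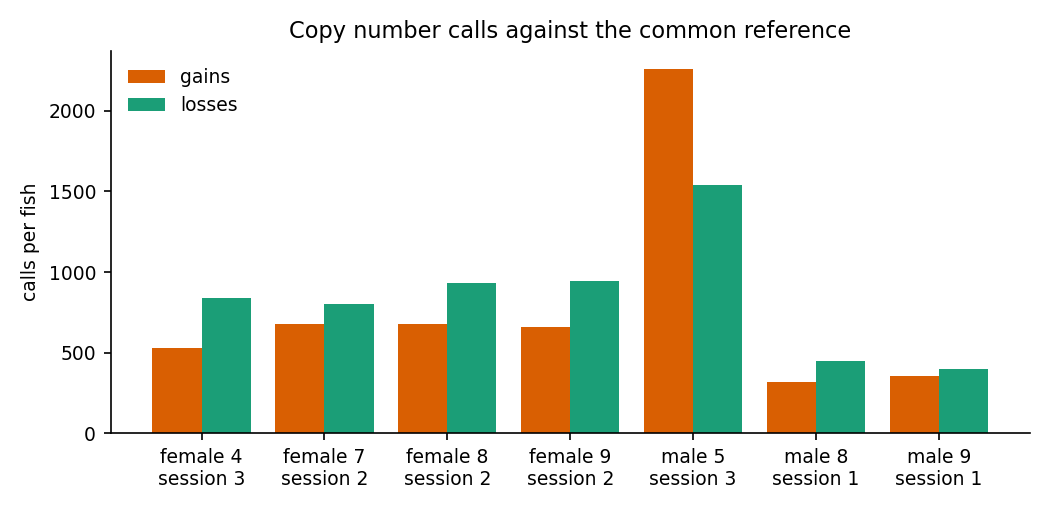
Bars give the number of gain and loss calls (vertical axis) in each of the 7 fish, with the scan session of its array under the name. Male 5 had 2260 gains, and the other 6 fish had between 316 and 678.

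The second question was which loci differed from the reference in the whole family. The calls of the 7 fish merged into 4094 regions, and 130 of these were called in one direction in all 7 fish, 82 as losses and 48 as gains. These shared regions had a median length of 51.9 kb and were most numerous on 4 chromosomes: 25 lay on chromosome 4, 17 on chromosome 3, 15 on chromosome 22 and 12 on chromosome 18. Per 10 Mb they numbered 3.62 on chromosome 22, 3.49 on chromosome 4, 2.79 on chromosome 3 and 2.44 on chromosome 18. Of the 25 on chromosome 4, 23 were losses and 23 lay in its distal part, the long arm that is known for its repeats and tandem gene copies, while chromosome 4 held 5.41% of the probes. On chromosome 22, 14 of the 15 were losses, whereas on chromosome 18 gains made up 8 of 12. Chromosomes 10 and 23 had none.

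The 12 shared regions with the largest mean ratios comprised 3 gains and 9 losses. The gains lay on chromosome 3 from 2566471 to 2576326 (log2 ratio 3.27 ± 1.27, SD, n = 7) and from 2463877 to 2478091 (3.26 ± 0.99), and on chromosome 14 from 29862801 to 29873063 (2.98 ± 0.91). Among the losses, 5 lay on chromosome 4, at 45020400 to 45026255 (-2.97 ± 0.84), 52084640 to 52095156 (-3.22 ± 0.75), 52740166 to 52747325 (-2.77 ± 0.74), 56094186 to 56098854 (-3.24 ± 0.79) and 57765958 to 57771345 (-3.17 ± 0.99). The other losses lay on chromosome 24 at 39517200 to 39525856 (-3.26 ± 0.72), chromosome 21 at 24579316 to 24586398 (-3.11 ± 0.99), chromosome 22 at 1471209 to 1485140 (-3.06 ± 0.75) and chromosome 3 at 3120311 to 3128430 (-3.01 ± 0.82). In the 3 gains the reference was well above background at 13.1% to 17.9% of probe readings, and in the 9 losses the fish were at 0% to 60%, so the size of these ratios was set partly by background and gives no copy number. Normexp background correction gave means of 1.07 to 1.30 for the gains and -1.85 to -1.49 for the losses. When dim reference probes were left out, the second chromosome 3 gain measured 0.10 on what remained of its probes. The first chromosome 3 gain and the chromosome 14 gain could then not be measured.

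**Figure D2:**
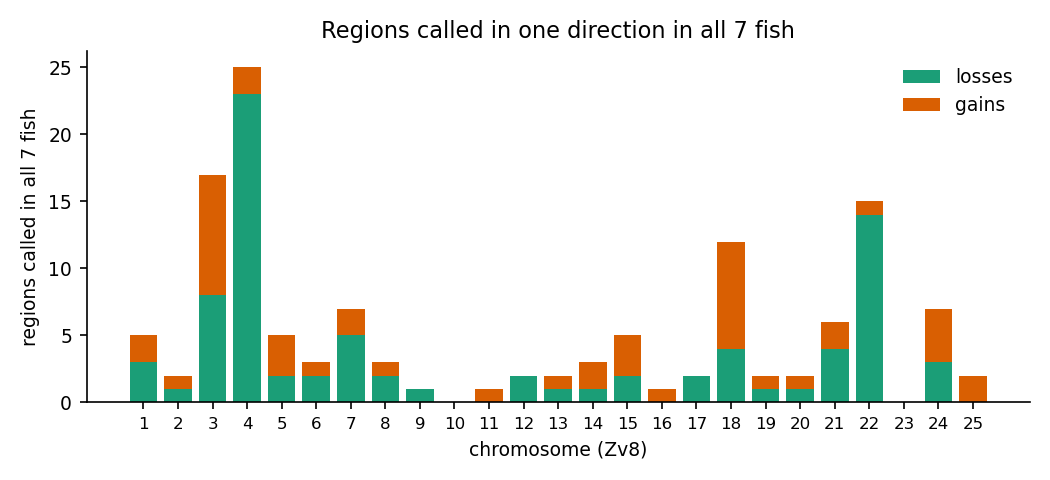
Bars give the number of regions called in one direction in all 7 fish (vertical axis) on each of the 25 chromosomes (horizontal axis, Zv8), split into losses and gains. Chromosome 4 had the tallest bar, with 23 losses and 2 gains.

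In total, 4145 probes were called in the same direction in all 7 fish, and none were when the calls of each fish were shifted independently along the genome 1000 times. All 7 ratios share the reference, so a locus at which the reference itself differs is called in every fish. At the other end, 2540 regions were called in 1 fish alone, and 1985 of these in male 5. Without male 5 there were 2274 regions.

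The share of probes in regions was highest on chromosome 4, followed by chromosomes 21 (43.7%), 23 (40.7%) and 8 (40.4%). The test set chromosome 4 against the other chromosomes pooled, not against the next highest. Regions covered 47.2% of its probes and 32.7% of the probes on the other chromosomes, a 1.44-fold difference that exceeded most of 1000 circular shifts of the region map (one-sided permutation p = 0.025). Without male 5 the shares were 28.5% and 14.8%, a 1.92-fold difference (permutation p = 0.016), and the normexp correction gave 2.89-fold (permutation p = 0.005). The shares themselves depended on slow trends of the ratio. They were 30.2% and 20.6% with the long running median subtracted, and 20.2% and 12.5% with the local one. The subtraction takes out slow drift and long copy number changes alike, so it does not tell how much of the coverage was drift. When the deviations of each fish from the probe's median over the 7 fish were segmented, which removes what the siblings share, the difference was 1.13-fold and did not pass (permutation p = 0.180).

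The third question was where full siblings differed from each other, since the common reference cancels in such differences. Of the 4094 regions, 2656 (64.9%) had a larger spread between siblings than windows of equal size outside the regions. The regions were called on the same arrays, most of them in 1 fish alone, and these windows hold no call, so the count describes the calls and is no independent test of variation. At most of the 12 regions with the largest spread, siblings fell into fish with strong signal and fish near background. On chromosome 1 from 3808665 to 3812980, females 4 and 7 and male 5 measured -3.81, -3.65 and -3.79, and none of their 5 probes was well above background, while the other 4 fish lay between -0.08 and 0.72 with all probes above it. On chromosome 17 from 19493047 to 19500430, females 4, 7 and 8 and male 9 measured -4.12, -4.90, -4.60 and -2.51, with 0% to 28.6% of probes well above background, and female 9 and males 5 and 8 measured -0.96, 0.19 and -0.05, with all probes above it. On chromosome 3 from 1019647 to 1024475, female 7 and male 9 both measured -0.19, and the other 5 fish measured -2.13 to -4.47. On chromosome 16 from 8592232 to 8601029, females 4, 7 and 9 and males 5 and 8 measured 2.13 to 4.70, against 0.43 in female 8 and -0.36 in male 9. Further along it, from 19266353 to 19271903, females 4 and 9 and male 8 measured -3.96, -4.36 and -2.47, and the other 4 fish -0.76 to 0.08. On chromosome 19 from 2191939 to 2199596, females 4 and 8 and males 5 and 9 measured 2.07 to 3.71, and the other 3 fish -0.51 to -0.40.

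A pair of regions on chromosome 9, at 30603905 to 30609228 and 30781386 to 30788173, had the same 3 lowest fish: females 4, 7 and 9 measured -3.38 to -4.28 in the first and -2.90 to -4.19 in the second, and the other 4 fish lay between -0.87 and 0.03 in both. On chromosome 13 from 21601190 to 21610959, females 7 and 8 measured -4.03 and -3.45, and the other 5 fish lay between -0.17 and 0.33. On chromosome 12 from 42020610 to 42034235, female 8 and males 8 and 9 measured 0.75, -0.08 and -0.13, and the other 4 fish -2.80 to -3.46. On chromosome 23 from 10820628 to 10825747, females 4, 8 and 9 and male 5 measured -5.08 to -4.06, and the other 3 fish -1.46 to -1.27. The region with the largest SD, on chromosome 3 from 7302392 to 7311112, split the fish by sex and is described with that comparison. Its first place depended on the processing: with normexp its SD was 0.92, against 1.14 on chromosome 17 from 19493047.

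**Figure D3:**
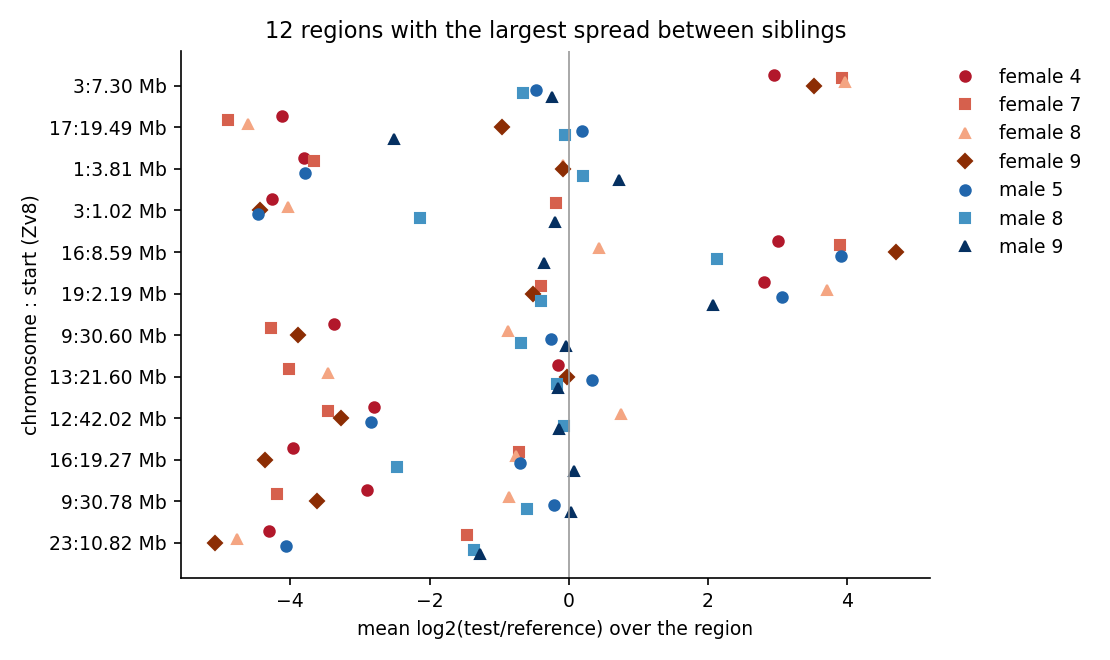
Points give the mean log2 ratio of test over reference (horizontal axis) of each of the 7 fish at the 12 regions with the largest spread between siblings (vertical axis, chromosome and start in Zv8). At 1:3.81 Mb, 3 fish lay at -3.81 to -3.65 and 4 fish at -0.08 to 0.72.

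Siblings also differed at some longer regions; 3 examples with at least 20 probes, chosen after their values were seen, are given here. On chromosome 15 from 42829379 to 42883971 (54.6 kb, 41 probes), females 4 and 8 and male 8 measured -2.87, -2.74 and -1.70, and the other 4 fish lay between -0.12 and 0.06. On chromosome 23 from 39527734 to 39589657 (61.9 kb, 46 probes), females 4 and 8 and males 5 and 8 measured 1.57, 2.49, 1.43 and 0.87, and the other 3 lay between -0.08 and 0.07. On chromosome 19 from 6724824 to 6759723 (34.9 kb, 27 probes) the siblings did not fall into such classes. All 7 fish were called as gains there, from 1.12 to 3.97. Scaling by array slope reduced the SD over fish of this region from 1.00 to 0.67. The reference was well above background at 14.3% of its probe readings and at 34.5% in the chromosome 23 region. The size of the ratios in both was therefore set partly by background.

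**Figure D4:**
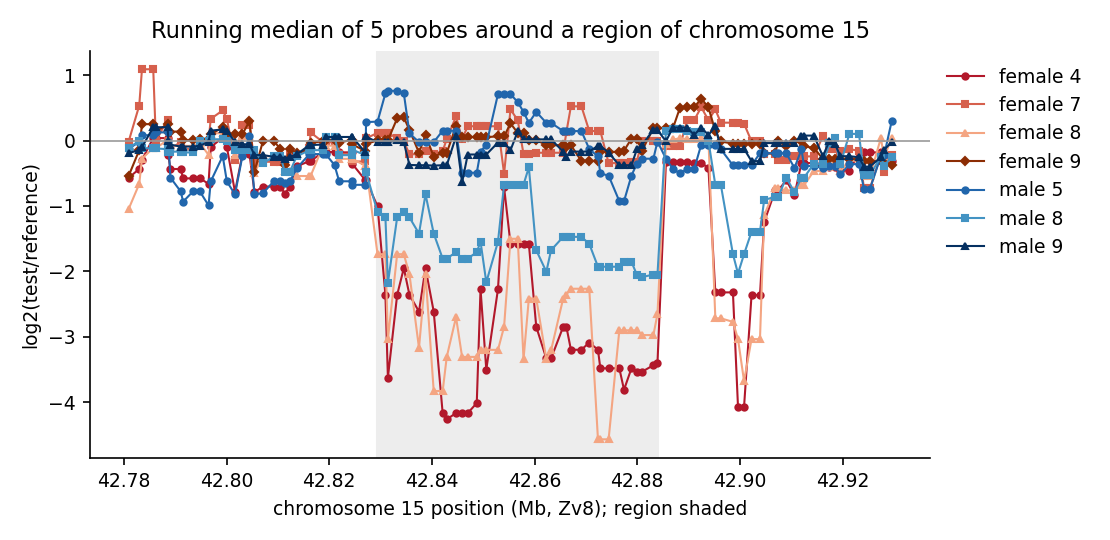
Lines give the running median over 5 probes of the log2 ratio of test over reference (vertical axis) along chromosome 15 (horizontal axis, Mb in Zv8) for the 7 fish, with the region shaded. Females 4 and 8 and male 8 drop inside the region, where their means were -2.87, -2.74 and -1.70.

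The 12 regions, chosen for their spread, had an SD over fish of 1.74 to 2.19. The count of varying regions was 1619 without male 5 and 1008 with a change point penalty of 4, and normexp reduced the 12 SDs to 0.82 to 1.14. The ratios of males 8 and 9 were smaller than those of the other fish at the regions called in all 7 fish, which adds to the spread there: 100 of the 130 varied, and 38 did once each array was scaled by its slope. The slopes were fitted on these same 130 regions, so a fall in their spread is partly built in.

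The fourth question was whether females and males differed in copy number. A single region passed the test: on chromosome 3 from 7302392 to 7311112 (8.72 kb, 8 probes), the 4 females measured 3.59 ± 0.48 (SD, n = 4) and the 3 males -0.45 ± 0.20 (SD, n = 3). The difference of 4.04 (SE 0.35) had an adjusted p of 0.00909 in limma over 4094 regions, and all 4 females lay above all 3 males. In the test channel, all 32 female probe readings in the region were well above background, against 2 of 24 male and 7 of 56 reference readings. The female signal was at least 2.26-fold the male signal, with the males set to the lowest signal well above background on their arrays; relative to the array median the measured log2 means were -0.79 and -3.57. Directly proximal, from 7283870 to 7300617, females measured 1.06 ± 0.19 and males -0.50 ± 0.40, and this region did not pass (limma, adjusted p = 0.111). The third-ranked region, on chromosome 6 from 39772543 to 39778096, measured 1.70 ± 0.25 in females and 0.35 ± 0.24 in males and did not pass either (limma, adjusted p = 0.258). The call on chromosome 3 depended on the processing. Without probes dim in the reference, only the region's probe from 7309295 was left. Its difference of 2.35 did not pass (limma, adjusted p = 0.259). With normexp the 8 probes of the region differed by 1.70 (limma, adjusted p = 0.00189). The calls then merged into a longer region, and no region passed. Over the 18 settings run on this region the limma adjusted p lay between 0.00189 and 0.259.

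**Figure D5:**
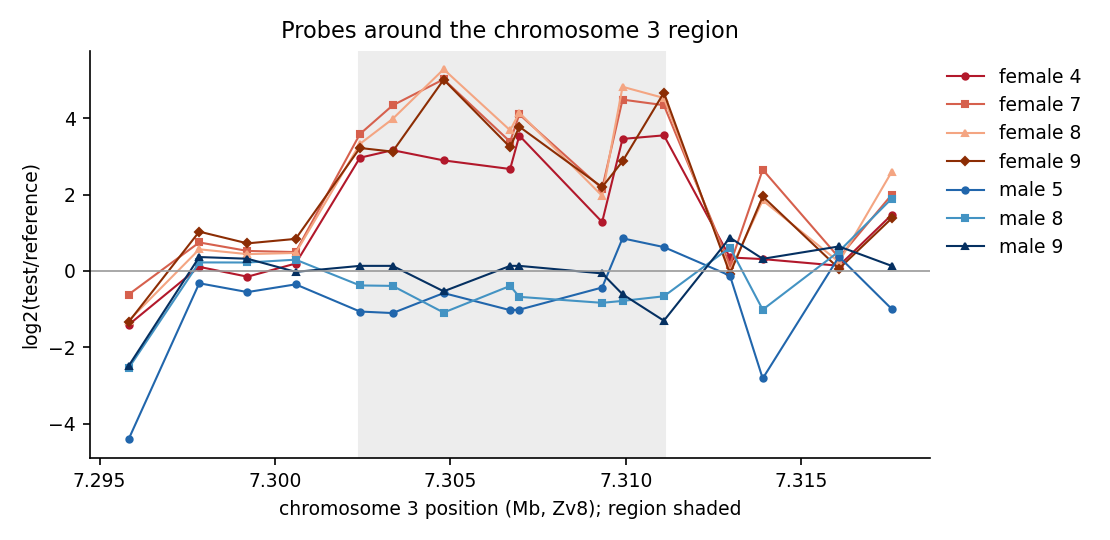
Lines give the log2 ratio of test over reference (vertical axis) of each of the 7 fish at the probes in and beside the chromosome 3 region (horizontal axis, Mb in Zv8), with the region shaded. Inside the region the means of the females lay between 2.94 and 3.97 and those of the males between -0.65 and -0.25.

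Windows of 25 probes, tested without regard to the calls, gave none that passed among 38504; 2566 had an unadjusted p below 0.05 in limma. The smallest adjusted p, 0.090, belonged to the window on chromosome 3 from 7282688 to 7316105, which holds the region above (females 1.80 ± 0.29, males -0.41 ± 0.33). The next 2 windows, on chromosome 6 from 27999013 to 28031484 and chromosome 9 from 28964062 to 28996743, differed by -0.43 and 0.60 with an adjusted p of 0.746 each in limma. On simulated windows with independent normal noise, the same test called 98 of 100 changes of 1.0 and 15 of 100 changes of 0.5. Smaller differences would be missed even there. The simulation held no session differences, and the real chromosome 3 window differed by 2.21 without passing. It therefore does not tell which real differences would be found. Sex was spread unevenly over 3 scan sessions, and only 1 session held both sexes, with female 4 and male 5. Between these 2 fish the chromosome 3 region differed by 3.41. With the session as a block in limma, 55 windows and 735 regions passed, but the estimate is then female 4 minus male 5, with the error taken from arrays of equal sex in the other 2 sessions, so these counts do not separate sex from other differences of that pair. Without male 8 or without male 9 no region passed. The chromosome 3 region then still differed by 3.95 and 4.15, with an adjusted p of 0.149 and 0.127 in limma on the 4094 regions. Without male 5 its adjusted p in limma was 0.0505 on these regions and 0.0286 among the 2274 regions called again, where 9 regions passed, with 4 windows. The males left were then the 2 arrays of session 1, which held no female, so sex cannot be told apart from that session there.

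The distal end of chromosome 4 was tested separately, because sex-linked sequence is known there in some zebrafish lines. Over the distal 10% of its probes (64492313 to 71656121, 5212 probes), females measured -0.05 ± 0.04 (SD, n = 4) and males -0.04 ± 0.04 (SD, n = 3). The difference of -0.00673 was well within the spread between fish (two-sided exact permutation test, p = 0.857). The distal 5% differed by -0.00289 (exact p = 0.971) and the distal 20% by -0.0612 (exact p = 0.171). Mean log2 ratios per fish of whole chromosomes lay between -0.10 and 0.10 on all 25, and the smallest exact permutation p between the sexes was 0.114 (0.381 after Benjamini-Hochberg adjustment). With 35 splits this test, like that of the distal end, gives no p below 0.0571, so no difference could have passed at 0.05.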

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

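The comparison of female 4 with male 5, the shuffling of probe order, the counts of other splits, and the corrections by a local running median, by probe length and by array slope were tests chosen after the result was seen. For 32 quantities, the gap of the most extreme fish to its nearest neighbour, over the range, was examined among the 4 females and all 7 siblings. Of the 64 comparisons, 8 were beyond the 95% limit, which independent normal values pass about 1 in 20 times. The quantities overlap and include the 12 regions chosen for their spread, so the 8 cannot be set against that rate. Male 5 was far from its siblings in calls (3801, against 753 to 1609), in gains (2260, against 316 to 678) and in the share of its probes in calls (25.6%, against 2.04% to 7.49%). Among females, female 4 was far from the others in gains (530, against 656 to 678), at the shared gain on chromosome 14 from 29862801 (2.67, against 3.74 to 3.93) and at 9 mitochondrial probes (log2 ratio 0.77, against -0.73 to -0.62). Female 4 was the only female of scan session 3 and the others were of session 2, so its differences cannot be told apart from the session. Also among females, female 7 stood apart on chromosome 3 from 1019647 (-0.19, against -4.44 to -4.03), and female 8 on chromosome 12 from 42020610 (0.75, against -3.46 to -2.80).

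The excess of calls in male 5 was not produced by independent noise, since shuffling its probes left 0.0316% of its calls. After a local running median was subtracted it still had 2.23 times the calls of the next fish, and after regression on probe length 2.24 times, so neither a long wave of the ratio nor probe length accounts for all of it. Probe length explained 4.47% of the variance of its ratios and 0.166% to 1.41% in the other fish. GC content could not be examined without the probe sequences, and a difference in DNA quality of this fish may remain among the explanations. No biological explanation was tested, because no group of the design holds male 5 alone.

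The chromosome 3 region from 7302392 was higher in all 4 females than in all 3 males by 4.04. Female 4 and male 5, both of session 3, differed by 3.41, which a difference between sessions alone would not give. The region was chosen on these same arrays and this is 1 pair, so the value is no independent test of the session. Among regions at which siblings fell into 2 classes, 2 had the sex split, both in this stretch of chromosome 3, and the most frequent other split into 4 and 3 fish had 4, so chance segregation among siblings could account for it. Of the 35 splits of the fish, 7 gave at least the 1 region that passed, the sex split included, with 4 regions at most in another split, so chance is not excluded. For windows the same count decides nothing, since a count of 0 for sex is reached by all 35 splits (3 at most in another split). A link of this region to sex stays open and needs more families.

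In the 2 arrays of scan session 1 the ratios were smaller: over the 130 regions called in all 7 fish, male 8 had a slope of 0.60 (95% bootstrap interval 0.57 to 0.63) and male 9 of 0.57 (0.54 to 0.59) on the median fish, and the other 5 fish 0.99 to 1.17. Sex cannot be the cause alone, because male 5 had 1.04. With only probes bright in the reference the higher of the 2 slopes was 0.614 (lowest other fish 0.996), and with only probes bright in both channels 0.757 (lowest other fish 1.07), so dim signals do not account for all of it. With normexp male 8 had 0.871 and male 9 had 0.743, which differed from the lowest other fish at 0.920 by -0.0489 (95% bootstrap interval -0.0989 to -0.0021) and -0.176 (-0.233 to -0.122), so background left in the processed signals is argued against as the whole cause. Part of it stays open, as does any other difference of the session, such as the multiplicative trend with its fit value of 0 on these 2 arrays, and no biological explanation was tested.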

How the results depend on the processing

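The local running median, probe length, Zv7 positions, array slope, deviations from the probe median and the run without both arrays of session 3 were tests chosen after the data were seen. Chromosome 4 stayed past its threshold in 19 of 20 settings (1.34 to 2.89-fold; 1.43 to 1.92 without single fish); segmenting the deviations from the probe median, which removes what the siblings share, gave 1.13-fold (permutation p = 0.180). A penalty of 4 gave 254 gains, 373 losses, 1275 regions, 67 in all fish and 1008 varying; at least 10 probes per call gave 431 gains, 531 losses and 75 regions in all fish. Without dim reference probes there were 215 gains and 665 losses per fish and 72 regions in all fish (17 gains, 55 losses), and with normexp 841 gains and 725 losses and 151 regions (71 gains, 80 losses). Merging at 50% overlap gave 6701 regions with 4573 varying. Regions covered 33.5% of all probes in the main setting, 21.1% with the long running median subtracted and 12.9% with the local one. Without both arrays of session 3 there were 2106 regions with 1506 varying; segmenting the deviations from the probe median gave 6197 varying. Without single fish, medians were 593 to 666.5 gains and 819 to 884 losses. There were 2274 to 4250 regions, with 1619 to 2875 varying, both lowest without male 5, and 136 to 166 in all remaining fish. Of the 2656 varying regions, 1976 still varied with normexp, 1368 without male 5 and 987 without both arrays of session 3.

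Sex comparisons moved most. Windows that passed numbered 1 with the long or the local running median, probe length, Zv7 positions, array slope or windows of 50 probes, 9 without session 3, 55 with session as a block and 0 to 4 without single fish. Regions that passed numbered 0 with normexp, without dim reference probes or with at least 10 probes (the chromosome 3 region has 8), 2 with the local running median or array slope, 380 without session 3, where sex and session coincide, 735 with session as a block, where the estimate is female 4 minus male 5 and the error comes from the other 5 arrays, and 0 to 9 without single fish. The 4 windows and 9 regions came without male 5, where the males left were all of session 1. At the fixed chromosome 3 region the difference was 1.70 with normexp (limma, adjusted p = 0.00189), where the calls merged into a longer region (47.3 kb). It was 2.35 without dim reference probes, which left only the probe from 7309295 (limma, adjusted p = 0.259). Over the 18 settings run on this region the limma adjusted p was 0.00189 to 0.259. The call of this region was lost in 6 alternatives: without dim reference probes, with the local running median (0.0534), with the replicate block (0.234) and without male 5 (0.0505), 8 (0.149) or 9 (0.127). Apart from the run without dim reference probes, its difference in these alternatives lay between 3.95 and 4.19. With the replicate block, 0 windows and 0 regions passed, with 1 residual degree of freedom, and distal chromosome 4 differed by -0.0167; numbers 8 and 9 name animals, and their female and male arrays correlated at 0.264 and 0.273, below female 4 with male 5 (0.618). The distal chromosome 4 difference changed sign with probe length (0.00473), array slope (0.00352) and session as a block (0.0396), and spanned -0.0306 to 0.00654 without single fish; its exact test gives no p below 0.0571 in 7 fish and could not pass. The cause of these changes was not tested otherwise. Of 349 alternatives for named regions, 328 kept the call or stayed within the spread, 15 moved, 0 changed sign and 6 lost the threshold, all 6 at that chromosome 3 region. This tally is no test of stability. The varying regions were chosen for a large spread, and shared regions counted as kept if they changed by less than their SD over fish. All named shared regions moved with normexp, and regions without a value in a setting were not counted. Gene lists were not run. Signal over background limits the size of ratios.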

Other observations

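The tests without chromosome 16, without male 5 or without scaling, the share of splits that divide a session, the scaling by array slope and the choice of the chromosome 16 and 7 events came after the results were seen. Male 9 carried gains that none of its siblings had, in 2 stretches of chromosome 16. From 24486688 to 24728739 (242 kb, 177 probes) it averaged 1.22 over all probes, with 8 called regions of 0.63 to 3.12, and the other 6 fish averaged 0.00 to 0.05. From 35100313 to 35313486 (213 kb, 156 probes) it averaged 1.55, with 7 called regions of 0.75 to 3.17, and the others -0.01 to 0.17. In the Zv7 assembly the most frequent sequence in both stretches was 1 unplaced scaffold, with 26.6% and 37.8% of their probes. On chromosome 7 from 8070518 to 8279009 (153 probes), female 4 and male 5 measured -1.77 and -1.81, and the other 5 fish -0.53 to -0.34. The same 2 fish were the lower ones at 8332461 to 8347981 (-3.73 and -3.93, against -0.92 to -0.66) and at 16861904 to 16870603 (-1.65 and -1.53, against -0.08 to 0.03). Female 4 and male 5 are the 2 arrays of scan session 3 and their windows, as deviations from the mean of their sex, correlated at 0.618, so these splits cannot be told apart from a difference of the session.

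The 9 probes that Zv7 places on the mitochondrial genome, 7 of which Zv8 places on chromosome 5, had mean log2 ratios of 0.77 in female 4 and 1.22 in male 5, the fish of scan session 3, and of -0.87 to -0.62 in the other 5 fish. Females averaged -0.31 ± 0.72 (SD, n = 4) and males -0.13 ± 1.17 (SD, n = 3; exact permutation p = 0.857). In both fish of session 3 the test signal of these probes was further above the array median than in the others (log2 5.74 and 6.16, against 4.22 to 5.05). The signal of the common reference was also lowest in these 2 arrays (4.90 and 4.94, against 5.00 to 5.09 in session 1 and 5.57 to 5.69 in session 2), so part of the difference in ratio from session 2 lies in the reference channel.

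With ratios scaled by array slope, 147 regions split the siblings into 2 classes with a gap of at least 1. Of these, 55 set 1 fish apart, 55 set 2 apart and 37 set 3 apart, and 40 of the 63 possible splits occurred. A candidate explanation is inheritance of linked blocks. It predicts that regions near each other share a split: of 38 pairs of regions 0.2 to 2 Mb apart, 50% had the same split, against 25.2% of 361 pairs over 10 Mb apart on the same chromosome, 3.69% of pairs on different chromosomes and at most 18.4% in 1000 reassignments of splits to regions (permutation p = 0.001, the smallest they can give). Without chromosome 16 the share was 45.7% of 35 pairs (permutation p = 0.001) and, over 10 Mb apart, 10.2% of 275 pairs. Pairs that are fragments of 1 long event would give the same result and may be among them. The most frequent split, male 9 alone, had 27 regions, or 12 without the regions of the 2 chromosome 16 stretches, and the splits by scan session had 9 at most and 15 of the 147 together, but these counts rest on the scaling, which removes a difference of session 1 by construction. Without scaling there were 139 such regions: male 9 alone had 12, of which 2 lay outside the stretches, and the most frequent split was that of the session 1 arrays with 20, so for these 20 a session effect cannot be told apart from a difference between the fish. Of the splits, 89.8% with scaling and 78.4% without it divided the arrays of a session, and the session alone does not give such a split. All of the 63 possible splits except those by session do so too, so these shares are high by default. They do not measure how much the session matters and do not argue against an effect of it. Without scaling the splits by session held 30 of the 139 regions together, more than equally frequent splits would give. Near pairs shared a split at 46.3% without scaling (permutation p = 0.001).

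Regions were more frequent near chromosome ends: they covered 72.2% of the probes in the terminal 2 Mb and 30.3% elsewhere, 2.38-fold more (permutation p = 0.001 in 1000 circular shifts, the smallest they can give). Without male 5 the shares were 30.6% and 14.3%, 2.14-fold (permutation p = 0.002). The shares were not measured with a running median subtracted. This is consistent with copy number change concentrated towards the ends, though an effect of base composition was not tested.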
